A study of Mus musculus with 72 samples.

How the data were processed

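Islets of male mice of C57BL/6J, DBA/2J and BALB/cJ were isolated by Liberase digestion and hand-picking and kept overnight in culture medium before RNA was extracted, per the labels. The RNA quality numbers were 8.2 to 9.3, and 250 ng of RNA per library went into stranded, poly(A)-selected preparation (TruSeq) and single-end sequencing of 125 bp on an Illumina HiSeq instrument. The submitters' processing notes name STAR 2.5.3a, HTSeq 0.9.1, edgeR (with no version) and the GRCm38 build. The series text gives the days as 5, 13 and 13, while the sample labels give days 5, 13 and 33, and the labels were used. A strain label spelled C56BL/6J was read as C57BL/6J.

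The deposited table holds log2 CPM values that the authors normalized between libraries, for 14604 genes and 69 libraries. All of its 69 columns matched a sample, and 3 of the 72 samples of the series (1 each of C57BL/6J RC day 33, DBA/2J HFD day 13 and DBA/2J RC day 33) had no column and were not analysed here, so those groups held 3 libraries. The scale was tested on the values: every library had one floor of -3.54 log2 CPM (0.0862 CPM), 19 to 67 genes per library lay at the floor, and linear values summed to 911117 to 1095150. From the floor, whole reads were recovered for 100% of the values of each library, within a tolerance of 0.05 reads. The recovered reads in the deposited genes numbered 12292621 to 34591079 per library (median 22756199), and the 10 most abundant genes took 22.3% to 33.4% of them. Chi-square per degree of freedom between replicates ran from 4.81 to 130.1, so replicates differed by more than counting error.

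Gene identifiers were matched without their version to GENCODE mouse release 21 (GRCm38). Of the identifiers 14589 matched, 12536 with the same version. For 62 genes the symbol was missing or had been turned into a date, and 47 of these symbols were taken from the annotation. Coordinates are those of the annotation. Nnt, which was to serve as a check of the strain labels, is not in the table and was not analysed here, so strains were checked by principal components.

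The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. A filter of log2 CPM above 0 (1 CPM) in at least 4 libraries removed no gene. A linear model with 1 mean per group was fitted to all 69 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend). Planned for 72 libraries, it used the 69 that have values. Contrasts were HFD minus RC averaged over all strains and days, within each strain over the days, and within each strain at each day, then the differences of these effects between strains and between days 33 and 5, and the strain differences under RC. The contrasts are two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with 0.05 as the threshold. Values after ± are standard errors for log2 changes and SD for group means.

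Named genes leave out predicted genes, pseudogenes, non-coding genes and the lowest 25% of genes by mean level. For averages over days they are the 10 highest and 10 lowest changes among genes past the threshold with one sign in every strain-by-day difference averaged. They are the 3 highest and 3 lowest at each day, the 6 lowest p for differences between strains, the 4 lowest p for differences between days, and the 8 highest and 8 lowest for strains under RC. Up to 4 members per list with the lowest p and fixed genes (Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Mafa, Pdx1, Nkx6-1, Slc2a2, Ucn3, Glp1r, Mki67, Cpt1a, Pdk4 and Nnt among them) were added. A few of the named genes are not reported here. A few other list members with their values were named to illustrate a list after their values were seen: Npas2, Hlf, Nfil3 and Nr1d2.

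The 31 gene lists cover islet function (beta-cell identity and function, exocytosis machinery, beta-cell disallowed genes), DNA replication and mitosis, lipids (cholesterol synthesis and uptake, fatty acid synthesis and desaturation, fatty acid oxidation and PPAR targets) and energy (glycolysis and lactate, oxidative phosphorylation). Others cover stress (ER chaperones and ER-associated degradation, integrated stress response, NRF2 and antioxidant genes, immediate early genes, hypoxia-inducible genes), immunity (chemokines and NF-kB targets, interferon-induced genes, Reg family), the circadian clock, cytosolic ribosomal proteins and mitochondrially encoded genes. Cell type lists are alpha, delta, PP and epsilon, acinar, ductal, endothelial, stellate cell and fibroblast, macrophage, lymphocyte, adipocyte and Schwann. Each was tested with camera in limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 31 lists. Member counts are given over all genes tested and adjusted over the list alone.

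On simulated data, 100 genes of 14604 were changed at each size of change in C57BL/6J over all days. The model recovered 76% of them at a log2 change of 0.5 and 97% at 1, with 6 false calls. At day 5 it recovered 57% and 84%, with 9 false calls. A list moved on purpose ranked 1 of 31 with 0 other lists called. The simulated noise was independent between genes, so this run does not show how camera behaves on correlated genes.

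Alternatives fixed beforehand were quantile normalization, libraries shifted to one median, a filter at a mean log2 CPM of 2 (11243 genes), array weights, robust empirical Bayes, the acinar score as a covariate, a block on title numbers that HFD and RC libraries share, each strain or pair of strains fitted alone, an estimated correlation, and each library left out in turn. A change of pseudocount was not run, since the values are already on the log2 scale, and a run with no filter is the reported one, since the filter removed no gene. Alternatives added after seeing the data were limma voom on the recovered reads, each day left out, the title number as a covariate within strain, the BALB/cJ title number series as a batch, libraries with outlying cell type scores left out, and scores of stellate cells and of macrophages and endothelial cells as covariates. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.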

Results

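Messenger RNA was sequenced from the pancreatic islets of male mice, 8 weeks old per the labels, of 3 inbred strains (C57BL/6J, DBA/2J and BALB/cJ) on a high-fat diet (HFD) or regular chow (RC) for 5, 13 or 33 days. Each library held RNA from 120 to 150 hand-picked islets of 1 mouse, so the p-values measure the spread between mice. The 69 libraries formed 18 groups of strain, diet and day. C57BL/6J RC day 33, DBA/2J HFD day 13 and DBA/2J RC day 33 held 3 libraries each, and the other 15 groups held 4 each. Levels of 14604 genes were compared as log2 CPM, where CPM are read counts scaled to one library size. The reads in these genes numbered 12292621 to 34591079 per library, with a median of 22756199. The insulin genes Ins1 and Ins2 took 11.5% to 23.3% of the reads of a library.

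Strain separated the libraries before diet did. The first principal component carried 38.6% of the variance and set the 23 C57BL/6J libraries (-60.3 to -46.3) apart from the DBA/2J and BALB/cJ libraries, which lay at 15.7 or above. The second carried 24.5% and set the 22 DBA/2J libraries (25.8 to 40.9) apart from the 24 BALB/cJ libraries (-40.2 to -31.5).

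**Figure D1:**
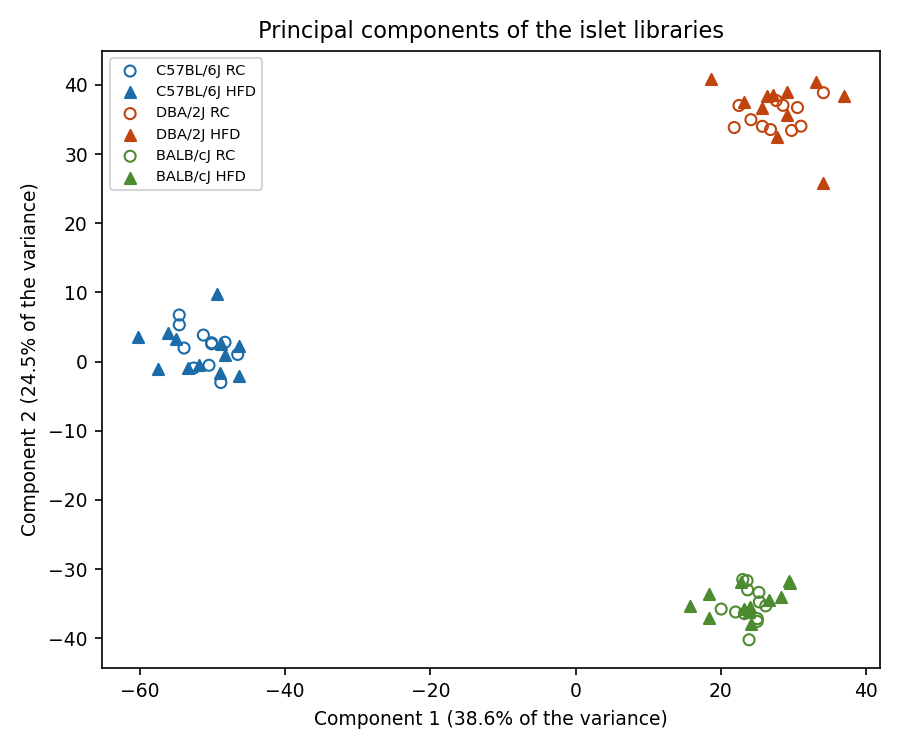
Each point is 1 library placed by its first and second principal component (share of the variance on each axis), with the strain as colour and the diet as marker. C57BL/6J lies at -46.3 or below on the first component, and the other strains part on the second.

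The design asks first which islet genes responded to HFD on average over strains and days, with 35 HFD and 34 RC libraries. Genes of the circadian clock were among those that changed. Dbp, a transcription factor that clock proteins drive, rose by 0.93 ± 0.13 on the log2 scale (SE, adjusted p = 1.3e-05 by limma with the Benjamini-Hochberg method), from 4.54 ± 0.64 log2 CPM (SD, n = 34) under RC to 5.48 ± 0.61 (SD, n = 35) under HFD. Arntl, which encodes the core clock activator BMAL1, fell by 0.75 ± 0.13 (adjusted p = 0.000117). Among the genes that fell were Fn1 (fibronectin) at -0.87, Col3a1 (a collagen chain) at -0.57 and the endoplasmic reticulum (ER) chaperone gene Hsp90b1 at -0.22 ± 0.04 (adjusted p = 0.00121). Pyy, the gene of the hormone peptide YY, rose by 0.48 ± 0.07 (adjusted p = 2.97e-05). In all, 799 of 14604 genes passed an adjusted p of 0.05, 352 higher and 447 lower under HFD.

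Among genes that moved one way in all 9 pairs of strain and day, Rbm3 rose most, by 0.57 ± 0.09 (adjusted p = 2.97e-05). Rbm3 (ENSMUSG00000031167.16, GRCm38 chromosome X from 8138975 to 8145880) encodes a cold-induced RNA-binding protein. It averaged 6.09 ± 0.38 log2 CPM (SD, n = 35) under HFD and 5.51 ± 0.55 (SD, n = 34) under RC. Pyy (ENSMUSG00000017311.15, chromosome 11 from 102106676 to 102107832) followed it. Smaller rises went to Pik3r5, a regulatory subunit of phosphoinositide 3-kinase (0.28), Cd164l2 (0.28), Net1, a guanine nucleotide exchange factor (0.22), and Efnb3, an ephrin (0.22). Fxyd6, a regulator of the sodium pump (0.22), Slc8a2, a sodium-calcium exchanger (0.21), and the kinase gene Pim3 (0.19) were also among the 10 highest. Tcim (ENSMUSG00000056313.5, chromosome 8 from 24437180 to 24438984), a small regulator of transcription, had the lowest adjusted p of these genes, at 9.69e-06, and fell by 0.51 ± 0.07. The other genes at the low end were Fn1, Col3a1, Postn (periostin, -0.44), the collagen genes Col5a2 (-0.42) and Col6a1 (-0.35), the linker histone gene Hist1h1e (-0.35), Egflam (-0.33), Thbd (thrombomodulin, -0.33) and Matn2 (matrilin, -0.32).

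The fixed gene lists were then tested as sets. Their camera calls rest on the preset correlation, and none for the average effects held with an estimated one. Of the 19 circadian clock genes 10 rose and 3 fell (12 and 5 adjusted over the list alone), with Tef at 0.54, Per3 at 0.69 and Npas2, a partner of the clock activator, at -1.01. The camera test of the list gave an adjusted p of 0.000279, and adjusted p = 0.135 with an estimated correlation. Of 38 genes of DNA replication and mitosis 11 fell and none rose (23 fell adjusted over the list alone), with a median of -0.26. Bub1, a spindle checkpoint kinase, stood at -0.60, Tpx2 at -0.57 and the proliferation marker Mki67 at -0.48. The list had a camera adjusted p of 5.29e-14, and adjusted p = 0.343 with an estimated correlation. Of 27 genes of ER chaperones and ER-associated degradation 7 fell and none rose (18 fell adjusted over the list alone), among them Pdia6, a disulfide isomerase (-0.22), Ero1lb, the beta-cell ER oxidase (-0.20), and Canx, calnexin (-0.12). Its median was -0.12 with a camera adjusted p of 4.38e-10, and adjusted p = 0.343 with an estimated correlation. Averaged over the days, limma called no member of this list in BALB/cJ or DBA/2J.

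Of 35 genes of fatty acid oxidation and PPAR targets 4 rose and none fell (7 rose adjusted over the list alone), led by the fatty acid binding protein gene Fabp4 (0.51 ± 0.10) and Acaa2 (0.22). The list passed camera at 2e-05, with adjusted p = 0.343 with an estimated correlation. In the exocytosis machinery 4 of 23 genes rose and none fell (4 adjusted over the list alone), with Vamp2 at 0.13, Cplx2 at 0.11 and Syt7 at 0.10 (camera 0.00352, adjusted p = 0.149 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 2 rose, Rps19 (0.10) and Rpl13 (0.13), and none passed adjusted over the list alone (camera 0.000215, adjusted p = 0.857 with an estimated correlation). Markers of cells other than beta cells moved as well. Of 17 stellate cell and fibroblast genes 5 fell (9 adjusted over the list alone), including Col1a1 (-0.65), Col1a2 (-0.42) and the pericyte gene Rgs5 (-0.17), with a median of -0.32 (camera 9.98e-08, adjusted p = 0.343 with an estimated correlation). Of 13 endothelial genes 2 fell, Pecam1 (-0.14) and Cdh5 (-0.15). The Cdh5 call ended in 32 of 69 removals of 1 library. Of 13 macrophage genes 1 fell, Lyz2 (-0.56), whose call ended without either of 2 C57BL/6J libraries. The endothelial list passed camera at 0.0328 and the macrophage list at 0.0398, each with adjusted p = 0.743 with an estimated correlation. With the stellate cell score as a covariate the endothelial median turned to 0.0103.

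Beta-cell identity showed no shift as a list: Isl1 rose (0.12), Ero1lb and Ucn3, the urocortin gene of mature beta cells (-0.14), fell, and 27 of 30 members were not called, with a camera adjusted p of 0.617. The other lists that missed the camera threshold held few called genes. Slc16a1, a lactate transporter gene that beta cells keep silent, rose (0.31) and Cxcl12 fell (-0.36) in the beta-cell disallowed list of 21 (0.332). Slc16a1 was also the only called gene among 17 of glycolysis and lactate (0.242). Atf4, a transcription factor of the integrated stress response, fell (-0.15) in its list of 25 (0.0542). Hmox1 (-0.26) and Nqo1 (-0.23) fell while Gclc (0.09) and Sod2 (0.08) rose among 21 NRF2 and antioxidant genes (0.936), where the median of -0.00, the mean and the test differed in sign. Ccn1 (-0.35) was called among 18 immediate early genes (0.185), P4ha1 (-0.26) among 13 hypoxia-inducible genes (0.752), Sod2 among 13 chemokines and NF-kB targets (0.763), and the interferon-induced Mx1 (-0.64) in a list of 26 (0.673) whose median and test differed in sign. No gene was called in the lists of cholesterol synthesis and uptake (0.479), fatty acid synthesis and desaturation (0.991, with median and test of unlike sign), the Reg family (0.129), mitochondrially encoded genes (0.936), delta cells (0.673), acinar cells (0.0821), ductal cells (0.991) and lymphocytes (0.332). The cell type lists of alpha cells (0.832), PP and epsilon cells (0.0881) and adipocytes (0.129) held 1 called gene each: Sphkap (-0.17), Pyy and Fabp4. Mki67 and Ucn3 were the fixed single genes past the threshold, and the hormone genes Ins1, Ins2, Iapp, Gcg, Sst and Ppy were not called. The Mki67 call ended in 30 of 69 removals of 1 library.

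Without C57BL/6J HFD day 33 replicate 1 the count of 799 became 1214, without day 5 it became 28, without day 33 439, and without libraries of outlying cell type scores 302. With array weights it was 3051, with the title number of each library as a covariate 428, with the stellate cell score 397, and with macrophage and endothelial scores 504. Of 63 called named genes, 14 lost their call without some single library. Among them were Rpl13 (in 49 of 69 removals), Sod2 (44), Col6a1 (40), Ccn1 (38) and Atf4 (25).

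**Figure D2:**
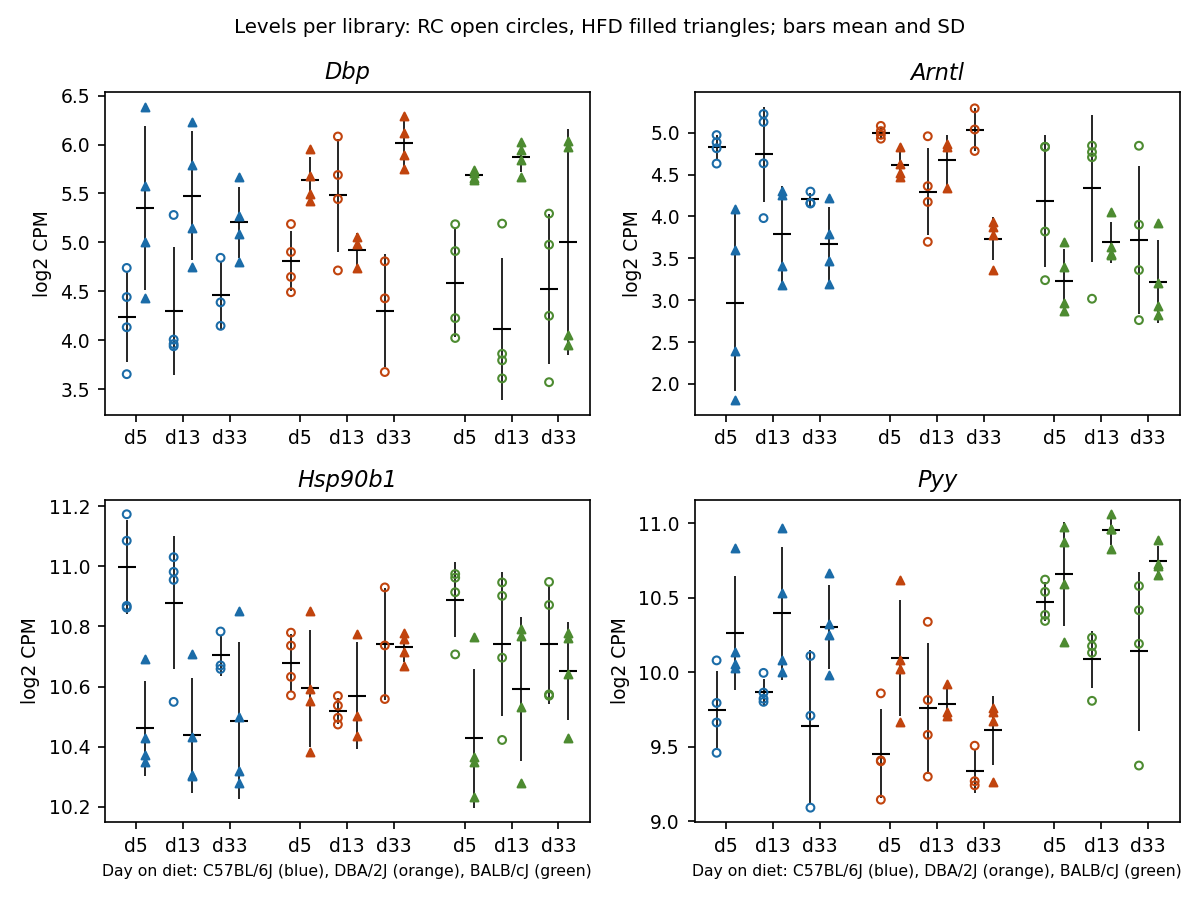
Levels of Dbp, Arntl, Hsp90b1 and Pyy in log2 CPM (vertical axis) are plotted by day on diet (horizontal axis) and strain (colour), with open circles for RC libraries, filled triangles for HFD libraries, and bars for the mean and SD of 3 or 4 libraries. Dbp in C57BL/6J at day 5 averaged 4.24 under RC and 5.35 under HFD, while in DBA/2J at day 13 it averaged 5.48 under RC and 4.93 under HFD.

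The next question was the response within each strain. C57BL/6J islets (12 HFD and 11 RC libraries) had 2125 called genes, 949 higher and 1176 lower. Of the clock genes, Per3 rose by 1.15 ± 0.20 (adjusted p = 0.000119), Dbp by 1.01 ± 0.23 (0.00207), Hlf by 0.90 and Per1 by 0.79 ± 0.13 (4.77e-05), while Npas2 fell by 1.87 ± 0.34 (0.000231), Nfil3 by 1.16 and Arntl by 1.11 ± 0.22 (0.000477). Per3 (ENSMUSG00000028957.12, chromosome 4 from 151003652 to 151044665) averaged 5.34 ± 0.61 log2 CPM (SD, n = 12) under HFD and 4.16 ± 0.42 (SD, n = 11) under RC. Rbm3 (0.89), the imprinted gene Nnat (0.81), the adenylyl cyclase gene Adcy1 (0.81), the protease gene Pcsk4 (0.73) and the matrix gene Ltbp2 (0.71) were the other high genes. Low genes were Fn1 (-1.44), Zdhhc22 (-1.25), Asb11 (-1.08 ± 0.17, adjusted p = 3.56e-05), the muscle cytochrome oxidase subunit Cox6a2 (-1.07), Col3a1 (-1.05), Col1a1 (-1.05), Ppp1r3c, a glycogen-targeting phosphatase subunit (-0.99), and Nckap5 (-0.99). The highest value was 1.43 ± 0.49 for Try5 (adjusted p = 0.0414), a trypsin gene of acinar cells from a family of near-identical copies.

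In C57BL/6J, several ER chaperone and stress response genes fell. Of 27 ER chaperone genes 13 fell and none rose (19 fell and 2 rose adjusted over the list alone), with Pdia6 at -0.47, Hsp90b1 at -0.40 and Canx at -0.30 ± 0.05 (adjusted p = 4.35e-05). The camera adjusted p of this list was 1.44e-07, and adjusted p = 0.685 with an estimated correlation. Of 25 genes of the integrated stress response 7 fell (12 fell and 1 rose adjusted over the list alone), including the serine pathway genes Phgdh (-0.64), Psat1 (-0.56) and Psph (-0.32) and the asparagine synthetase gene Asns (-0.35), with a camera adjusted p of 0.000451, and adjusted p = 0.685 with an estimated correlation. In oxidative phosphorylation 8 of 62 genes fell (8 adjusted over the list alone), such as Ndufb3 (-0.19) and Uqcrc2 (-0.15). Of 21 NRF2 and antioxidant genes 3 fell, Hmox1 (-0.59), Nqo1 (-0.53) and Prdx1 (-0.18). The exocytosis machinery went both ways, with 8 of 23 genes higher, among them the calcium channel genes Cacna1a (0.28) and Cacna1d (0.21), and Nsf lower (-0.16). The camera adjusted p was 0.000333 for oxidative phosphorylation (adjusted p = 0.711 with an estimated correlation), 0.0266 for NRF2 genes (adjusted p = 0.685 with an estimated correlation) and 0.0142 for exocytosis (adjusted p = 0.38 with an estimated correlation).

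The C57BL/6J clock list had 7 genes up and 4 down of 19 (camera 0.00757, adjusted p = 0.38 with an estimated correlation), with Per2 at 0.67. Of 38 replication genes 5 fell, including Rrm1 (-0.22), Rrm2 (-0.44) and Spc25 (-0.47) (0.000479, adjusted p = 0.711 with an estimated correlation). Beside these, markers of other cells differed between the diets. The acinar list had a median of 0.68 with 1 of 25 genes called (0.000333, adjusted p = 0.711 with an estimated correlation), and 7 of 17 stellate cell and fibroblast genes fell, with a median of -0.49 (0.000333, adjusted p = 0.705 with an estimated correlation). The macrophage genes Lyz2 (-0.98) and Adgre1 (-0.38) fell (0.0235, adjusted p = 0.705 with an estimated correlation), as did the endothelial genes Pecam1 (-0.22) and Emcn (-0.19) (0.0269, adjusted p = 0.711 with an estimated correlation). In lists past no camera threshold, Gipr, the receptor of the incretin GIP, rose (0.52), as did the glucose-sensing transcription factor gene Mlxipl (0.54), while the lipid droplet gene Plin2 (-0.37), Ucn3 (-0.27), the interleukin gene Il1b (-0.73), Tnfaip3 (-0.51) and Pdyn, a delta-cell peptide gene (-0.88), fell.

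Without day 5 the C57BL/6J count was 641 and without day 13 it was 581, and it was 1298 without HFD day 33 replicate 2 and 1361 without RC day 33 replicate 1. With macrophage and endothelial scores as covariates it was 1031, with array weights 4876, and with the title number as a covariate 31. RC day 33 replicate 4 had a mean macrophage level of 3.74 log2 CPM, against 2.65 and 2.77 in the other libraries of its group. Without it the calls of Fn1 (-0.80, adjusted p = 0.0756), Col1a1 (-0.88, 0.0586) and Lyz2 (-0.68, 0.093) ended, and so did that of Adgre1 (-0.26), which also ended without HFD day 13 replicate 4. With the title number Fn1 turned to 1.05, Asns to 0.0159, Il1b to 0.0571, Tnfaip3 to 0.0499 and Lyz2 to 0.0891, none of them called. With the macrophage and endothelial scores the stellate cell list had a median of -0.0426, and its test turned upward.

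BALB/cJ islets (12 libraries per diet) had 22 called genes, 16 higher and 6 lower. The clock genes among them were Dbp at 1.11 ± 0.22 (adjusted p = 0.0102), Nr1d1 (a repressor of Arntl) at 1.06, Tef at 0.60 and Bhlhe41 at 0.35. Depp1 (0.68), Adcy1 (0.66), Pyy (0.55), Mylip, a ubiquitin ligase of the LDL receptor (0.40), the aminopeptidase gene Anpep (0.40) and Rsad1 (0.29) also rose. The coagulation factor gene F13a1 (-0.90), Tcim (-0.60), C8b, a complement component (-0.38 ± 0.06, adjusted p = 0.0042), and Map10 (-0.33) fell. Of 14 called named genes 7 kept their call without any 1 library. The Adcy1 and Depp1 calls each ended in 16 of 24 removals, Tef in 14, Pyy in 9, Nr1d1 and F13a1 in 5 each and Map10 in 1. The camera test placed the ER chaperone list lower (median -0.17, 4.41e-13, adjusted p = 0.284 with an estimated correlation), with none of 27 members called and 9 lower adjusted over the list alone. It placed replication genes lower (-0.31, 6.62e-11, adjusted p = 0.425 with an estimated correlation), cholesterol synthesis lower (-0.10, 9.39e-07, adjusted p = 0.425 with an estimated correlation) and stellate cell genes lower (-0.20, 0.00215, adjusted p = 0.846 with an estimated correlation). At days 5 and 13 only the early-numbered HFD libraries had low means of the replication list (0.45 to 1.04 log2 CPM), and the late-numbered ones (1.71 to 2.29) lay within or above the RC range (1.49 to 2.20). Fatty acid oxidation was higher (0.13, 2.92e-10), with 7 of 35 members higher adjusted over the list alone, and so was the clock list (0.12, 0.00118), with 4 of 19 called. Both gave adjusted p = 0.135 with an estimated correlation. The count of 22 was 10 without RC day 13 replicate 1, 58 without HFD day 5 replicate 4, 4 without day 13, 3 with the strain fitted alone, 0 without the libraries of outlying cell type scores and 80 with the title number series of this strain as a batch.

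In DBA/2J islets (11 libraries per diet) limma called 0 genes, with 599 at an unadjusted p under 0.05, and voom called 0. The lists still leaned: all 35 fatty acid oxidation genes had positive estimates (median 0.11, camera 3.37e-09), as had 60 of 62 oxidative phosphorylation genes (0.08, 1.5e-15), 80 of 82 ribosomal protein genes (0.07, 7.53e-11) and 16 of 17 glycolysis genes (0.08, 1.95e-05). Replication genes were lower (-0.23, 2.38e-10), as were the stellate cell (-0.25, 0.000119), Schwann cell (-0.37, 0.00338), Reg family (-0.77, 0.0136) and acinar lists (-0.28, 0.0497), while NRF2 genes were higher (0.06, 0.00375). With an estimated correlation the lowest of these was adjusted p = 0.367, and no member of any list was called, including adjusted over the list alone. With array weights the DBA/2J count was 159, and without day 13 it was 5.

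**Figure D3:**
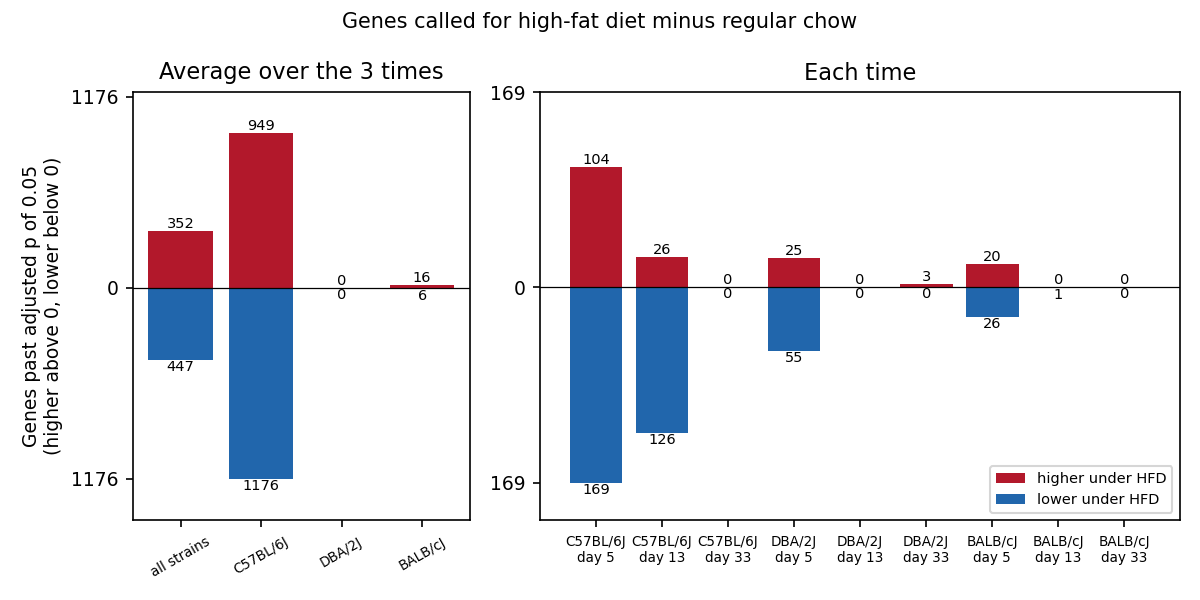
Bars give the number of genes past an adjusted p of 0.05 (vertical axis) for HFD minus RC, averaged over the days on the left and at each day on the right, with genes higher under HFD above 0 and lower ones below. C57BL/6J had 2125 called genes, BALB/cJ 22 and DBA/2J 0.

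**Figure D4:**
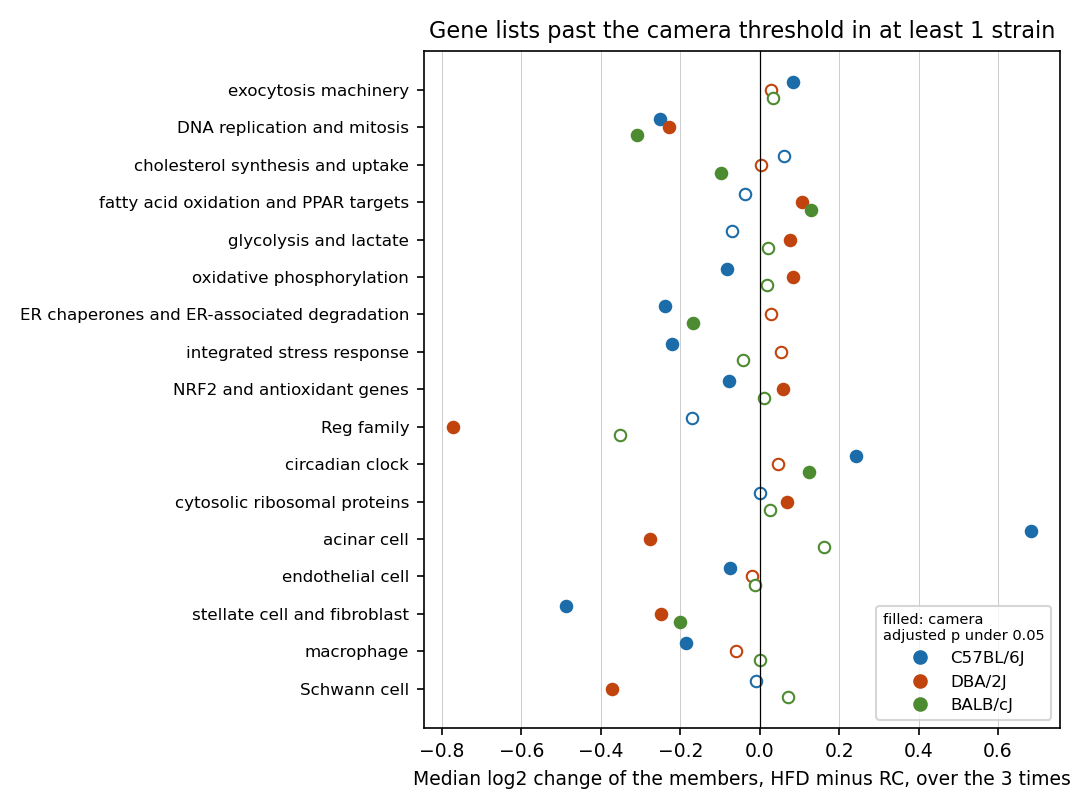
Points give the median log2 change of the members of 17 gene lists (vertical axis) for HFD minus RC in each strain (colour), filled where the camera adjusted p was under 0.05. The ER chaperone list lay at -0.24 in C57BL/6J and -0.17 in BALB/cJ, and the acinar list at 0.68 in C57BL/6J and -0.28 in DBA/2J.

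At each day the design compared 4 HFD with 4 RC libraries or, where 1 group held fewer, 4 with 3. At day 5 in C57BL/6J, 104 genes rose and 169 fell. Per1 rose by 1.67 ± 0.21 (adjusted p = 1.07e-06), Per3 by 1.55 and the kinase gene Sik1 by 1.46, while Nfil3 (-1.94), Arntl (-1.85) and Ppp1r3c (-1.69) fell. The Sik1 call ended in 7 of 8 removals of 1 library, and those of Nfil3 and Ppp1r3c in 2 each. Of 18 immediate early genes 1 fell (10 adjusted over the list alone), with a median of -0.90 (3.61e-06, adjusted p = 0.289 with an estimated correlation). Of 13 chemokines and NF-kB targets 3 fell, with a median of -0.40 (1.24e-05, adjusted p = 0.252 with an estimated correlation), and the stellate cell list had a median of -1.04 (7.49e-06, adjusted p = 0.425 with an estimated correlation). At day 13, 152 genes were called, 26 higher and 126 lower: Per3 (1.40), Rbm3 (1.30) and Hlf (1.14) rose, and Cox6a2 (-1.66), Pdyn (-1.47), Ovol2 (-1.36) and Ucn3 (-0.67 ± 0.11, adjusted p = 0.00163) fell. Of 25 cholesterol genes 1 rose (8 rose and 1 fell adjusted over the list alone), with a median of 0.28 (5.46e-09, adjusted p = 0.415 with an estimated correlation). HFD replicates 3 and 4 carried this, with mean levels of 5.52 and 5.57 log2 CPM over the list, while replicates 1 (5.08) and 2 (5.03) lay within the RC range (4.99 to 5.10). The acinar median at day 13 was 1.92 (7.51e-11, adjusted p = 0.465 with an estimated correlation). At day 33 limma called 0 genes, with 2180 at an unadjusted p under 0.05, and voom called 11. Without HFD day 5 replicate 4 the day 5 count was 61, without HFD day 13 replicate 4 the day 13 count was 0, and without HFD day 33 replicate 1 the day 33 count was 1134. At day 5 the HFD and RC libraries of C57BL/6J carry title numbers that do not overlap, so a processing series and the diet cannot be told apart there.

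BALB/cJ islets at day 5 had 46 called genes, 20 higher and 26 lower. The fatty acid desaturase gene Scd1 (1.69 ± 0.31, adjusted p = 0.0159), Fabp4 (1.23) and Fmo5 (0.74) rose, and Derl3 (-1.40) and Sdf2l1 (-1.11), both of ER quality control, and Ovol2 (-1.33) fell. Scd1 and Fabp4 had SDs of 1.40 and 1.01 under HFD, against 0.35 and 0.46 under RC. The Scd1 call ended in 3 of 8 removals of 1 library, and those of Fabp4 and Fmo5 in 5 each. Of 27 ER chaperone genes 10 fell and none rose (24 fell adjusted over the list alone), with a median of -0.45. This list kept its camera call (2.09e-32) with an estimated correlation (adjusted p = 0.0234). HFD replicates 1 and 2, which carry earlier title numbers, had the lowest list means (7.97 and 7.99 log2 CPM), replicate 3 (8.43) lay below the RC range (8.63 to 8.87), and replicate 4 (8.66) within it. The acinar list had a median of 1.41 in the same comparison (4.81e-06, adjusted p = 0.753 with an estimated correlation). HFD replicates 3 (10.32) and 4 (9.56), which carry later title numbers, lay above the RC range of the list mean (5.23 to 7.93 log2 CPM), and replicates 1 (6.25) and 2 (5.67) within it. At day 13 only C8b was called (-0.60 ± 0.11, adjusted p = 0.0192), and at day 33 limma called 0 genes, with 669 at an unadjusted p under 0.05, and voom called 0. DBA/2J islets at day 5 had 80 called genes, 25 higher and 55 lower, with Fev, a serotonergic transcription factor gene (0.72), Ankrd13b (0.69) and Prrt3 (0.56) up and Thsd7a (-1.03), the BMP receptor gene Bmpr2 (-0.65) and Rnf180 (-0.64) down. At day 13 limma called 0 genes in DBA/2J, with 599 at an unadjusted p under 0.05, and voom called 0. At day 33, 3 genes rose, each with adjusted p = 0.0366: Nr1d2, a clock repressor gene (1.51 ± 0.31), and the low-level genes Zfp982 (1.45) and Adgrd1 (1.40), named after their values were seen. The Nr1d2 call ended without any 1 of the 7 libraries, and voom, robust empirical Bayes and the stricter filter called 0 genes. The BALB/cJ day 5 count was 0 without HFD replicate 1 or RC replicate 1 and 356 without HFD replicate 4. The DBA/2J day 5 count was 0 without HFD replicate 3 or 4 or RC replicate 1, 2 or 4, and 1657 without HFD replicate 2.

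The HFD responses were then compared between strains by the test of the difference itself. Between DBA/2J and C57BL/6J 162 genes differed, 95 with a more positive change in DBA/2J and 67 with a more negative one. The lowest p values went to Rtn4, an ER-shaping protein gene (0.39 ± 0.07), and the adenosine kinase gene Adk (0.33 ± 0.06), each with adjusted p = 0.0153, and then to Fgl2 (0.52), Pnrc1 (0.40), the meiotic gene Msh5 (-0.80) and Fuca2 (0.28). Canx (0.31), Phgdh (0.64) and Psph (0.37) fell in C57BL/6J and differed upward in DBA/2J, while Per1 (-0.79), Per2 (-0.73), Gipr (-0.59) and Mlxipl (-0.58) differed downward. Of 15 called named genes 2 kept their call without any 1 library. The Phgdh call ended in 31 of 45 removals, Gipr in 28, Psph in 25, Mlxipl in 22, Per2 in 11, Per1 in 9 and Canx in 4. By camera the lists of oxidative phosphorylation (median 0.17, 3.28e-13) and ER chaperones (0.27, 1.14e-08) differed upward, and the acinar list downward (-0.97, 1.2e-05). The first 2 gave adjusted p = 0.597 and the third adjusted p = 0.752 with an estimated correlation.

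Between BALB/cJ and C57BL/6J 186 genes differed, 80 upward in BALB/cJ and 106 downward. Phgdh (0.90 ± 0.17) and Tmem215 (0.34) were more positive in BALB/cJ and Odf2 (-0.31) more negative, each with adjusted p = 0.00735, and Slc20a1, a phosphate transporter gene (-0.50), Rhpn2 (0.31) and Myo19 (-0.52) followed. Psat1 (0.83), Nqo1 (0.54), Pdk4, a brake on pyruvate oxidation (0.78), and Me1 (0.36) differed upward, and Mlxipl (-0.63), Per1 (-0.76) and Lss, a cholesterol synthesis gene (-0.32), downward. Of 16 called named genes 6 kept their call without any 1 library. The Lss call ended in 30 of 47 removals, Nqo1 in 22, Pdk4 in 19, Me1 in 18, Mlxipl in 5, and Psat1 and Per1 in 3 each. The cholesterol list differed downward (-0.14, 3.54e-05, adjusted p = 0.797 with an estimated correlation) and the fatty acid oxidation list upward (0.16, 8.08e-05, adjusted p = 0.783 with an estimated correlation). Between BALB/cJ and DBA/2J limma called 0 genes, with 472 at an unadjusted p under 0.05, and voom called 0. Without C57BL/6J HFD day 33 replicate 2 the count against DBA/2J was 5 and that against BALB/cJ 15, and with the title number as a covariate both were 0. Without libraries of outlying cell type scores the DBA/2J count was 3, and with macrophage and endothelial scores as covariates the counts were 8 and 13.

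Across all 14604 genes, which are not independent replicates, the changes of BALB/cJ and DBA/2J had a Pearson r of 0.352, those of C57BL/6J and BALB/cJ 0.193 and those of C57BL/6J and DBA/2J 0.088. All 22 genes called in BALB/cJ had the same sign of change in both other strains. Of the 2125 genes called in C57BL/6J, 1320 (62.1%) had the same sign in BALB/cJ and 1096 (51.6%) in DBA/2J, against 55.4% and 51.5% of all genes.

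Whether the response changed with time was tested as day 33 minus day 5. In C57BL/6J 3 genes differed, all downward, including Per1 (-1.57 ± 0.31, adjusted p = 0.0304) and the pseudokinase gene Trib1 (-1.05 ± 0.20, adjusted p = 0.0246). The third, the low-level DNA polymerase gene Pole (-2.44), was named after its value was seen. The replication list differed downward (-0.86, 2.71e-12, adjusted p = 0.45 with an estimated correlation) and the chemokine list upward (0.87, 3.12e-07, adjusted p = 0.128 with an estimated correlation). In DBA/2J 2 genes differed upward, Ino80c (0.66) and Arl6ip6 (0.70), each with adjusted p = 0.0488. In BALB/cJ limma called 0 genes, with 706 at an unadjusted p under 0.05, and voom called 0. The DBA/2J count was 1060 without HFD day 5 replicate 2 and 0 with voom, and the C57BL/6J count was 0 with the title number as a covariate and 7 with voom.

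The strains themselves were compared under RC. DBA/2J differed from C57BL/6J in 7954 genes, 3928 higher and 4026 lower. Pianp (ENSMUSG00000030329.11, chromosome 6 from 124996694 to 125003096), a ligand of an inhibitory immune receptor, was higher by 6.87 ± 0.12 (adjusted p = 4.17e-48), at 6.77 ± 0.15 log2 CPM (SD, n = 11) against -0.09 ± 0.47 (SD, n = 11). The digestive protease gene Ctrc (7.41), Tpm3-rs7 (6.05), Stab2, a scavenger receptor (5.39), Tex15 (4.74), Trnp1 (4.60), the sulfate transporter gene Slc26a1 (4.22) and Angptl7 (4.03) were also higher. The histocompatibility gene H2-Q2 (-5.60), the collagen gene Col6a6 (-5.83), the folate receptor gene Folr1 (-5.28), Rnf150 (-3.72), Tceanc2 (-3.21), Rpl29 (-3.02), Rab6b (-2.91) and Ptprt (-2.84) were lower. Of the beta-cell genes fixed beforehand, Mafa (0.87), Glp1r (0.61) and Pdx1 (0.17) were higher and the glucose transporter gene Slc2a2 (-0.29) lower. Of 25 acinar genes 23 were higher (median 1.67, 0.000365), of 82 ribosomal protein genes 66 higher and 8 lower (0.30, 2.47e-07), of 62 oxidative phosphorylation genes 39 higher and 2 lower (0.21, 1.07e-05), and of 9 mitochondrially encoded genes 8 lower (-0.52, 0.00116). Each of these lists gave adjusted p = 0.993 with an estimated correlation.

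BALB/cJ differed from C57BL/6J in 8225 genes, 4047 higher and 4178 lower. Pianp (7.02), Ctrc (6.81), Tpm3-rs7 (6.05), Tex15 (4.78), Angptl7 (4.30), Slc26a1 (4.15), Trnp1 (4.14) and Fmo2 (3.59) were higher, and H2-Q2 (-5.32), Msln (-4.93), Col6a6 (-4.79), Rnf150 (-4.31), Rpl26 (-3.73), Prom1 (-3.65), the deiodinase gene Dio1 (-3.35) and Rec8 (-2.98) lower. Mafa (1.06), Sst (0.71), Ppy (0.65), Gcg (0.49) and Ins1 (0.45) were higher and Slc2a2 (-0.44) lower. Of 27 ER chaperone genes 18 were higher and 1 lower (0.36, 0.00151, adjusted p = 0.864 with an estimated correlation), and of 17 stellate cell genes 15 higher and 1 lower (0.87, 0.00151, adjusted p = 0.864 with an estimated correlation). Of 9 mitochondrially encoded genes 8 were lower (-0.38, 0.0156, adjusted p = 0.864 with an estimated correlation), of which mt-Co1 turned to 0.13 under quantile normalization.

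BALB/cJ differed from DBA/2J in 5113 genes, 2534 higher and 2579 lower. Folr1 (5.36), the neuropeptide gene Npy (3.13), Tceanc2 (3.08), C1qtnf1 (2.87), Plekha4 (2.84), the fatty acid elongase gene Elovl4 (2.62) and Kcnip3 (2.57) were higher. Stab2 (-6.16), Rpl26 (-4.19), the creatine kinase gene Ckb (-3.36), Msln (-3.28), Dio1 (-3.21), Wdr49 (-3.05), Snhg11 (-3.02) and Tnfrsf11b (-2.92) were lower. Of 27 ER chaperone genes 18 were higher and none lower (0.31, 0.00028, adjusted p = 0.926 with an estimated correlation), and of 7 delta-cell genes 6 were higher (0.44, 0.0326, adjusted p = 0.68 with an estimated correlation). Reads of all strains were aligned to the GRCm38 build, which is C57BL/6J sequence. Strain variants and near-identical copies therefore limit what H2-Q2, Tpm3-rs7, Rpl26 and Rpl29 show. With macrophage and endothelial scores as covariates the counts against C57BL/6J were 3382 for DBA/2J and 3726 for BALB/cJ. Under RC the mean endothelial level was at most 5.21 log2 CPM in C57BL/6J, but at least 5.28 in DBA/2J and 5.32 in BALB/cJ. The covariate thus goes with strain, and these counts cannot show whether the strain differences depend on cell content.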

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

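Voom, the runs without a day and those with the title number or with stellate cell, macrophage and endothelial scores as covariates were chosen only after the results were seen, while the other tests in this part were fixed earlier. Libraries far from the others of their group were sought in 450 tests, 30 measures in each of the 15 groups of 4, by the gap to the nearest library over the range. Of these 23 passed, against 22.5 that chance gives at 1 in 20. Cell type values are mean log2 CPM of the list, and gene values are log2 CPM.

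In C57BL/6J HFD day 5, replicate 3 had Mafa at 5.42 (others 6.55 to 6.66) and Nkx6-1 at 8.52 (8.40 to 8.42). In C57BL/6J HFD day 13, replicate 3 had a lymphocyte value of 3.51 (0.86 to 0.93) and replicate 1 had Ppy at 11.25 (11.71 to 11.77). C57BL/6J HFD day 33 replicate 3 had an endothelial value of 5.22 (4.96 to 5.01), and C57BL/6J RC day 5 replicate 1 had Mki67 at 2.66 (3.77 to 3.87). In C57BL/6J RC day 13, replicate 2 had a delta-cell value of 4.69 (4.64 to 4.65) and a second component of -0.525 (2.58 to 2.80), and replicate 3 had a first component of -48.3 (-50.5 to -50.1) and Gcg at 14.85 (15.07 to 15.09). DBA/2J HFD day 33 replicate 1 had an endothelial value of 5.85 (5.36 to 5.42), an adipocyte value of 4.10 (3.53 to 3.60) and Nkx6-1 at 8.28 (8.42 in each of the others). In DBA/2J HFD day 5, replicate 3 had a ductal value of 3.53 (3.22 to 3.23), replicate 4 a second component of 40.4 (38.4 to 38.6) and replicate 1 Mki67 at 2.71 (3.64 to 3.80). In DBA/2J RC, day 13 replicate 3 had Glp1r at 7.90 (8.47 to 8.56), day 13 replicate 1 Pdk4 at 5.78 (5.20 to 5.29) and day 5 replicate 2 Ppy at 12.20 (11.44 to 11.53). In BALB/cJ RC, day 13 replicate 1 had an endothelial value of 5.60 (5.41 to 5.43), day 33 replicate 3 a macrophage value of 2.64 (2.43 in each of the others) and day 33 replicate 4 a lymphocyte value of 1.04 (-0.32 to -0.09).

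The test of the difference itself set HFD responses apart between strains and between days. DBA/2J minus C57BL/6J gave Rtn4 0.39, Adk 0.33, Fgl2 0.52, Pnrc1 0.40, Msh5 -0.80 and Fuca2 0.28. Without C57BL/6J HFD day 33 replicate 2 the calls of Fgl2, Pnrc1, Msh5 and Fuca2 ended, each with a limma adjusted p of 0.0577. BALB/cJ minus C57BL/6J gave Tmem215 0.34, Phgdh 0.90, Odf2 -0.31, Slc20a1 -0.50, Rhpn2 0.31 and Myo19 -0.52. Day 33 minus day 5 gave Trib1 -1.05 and Per1 -1.57 in C57BL/6J, and Ino80c 0.66 and Arl6ip6 0.70 in DBA/2J. Of 15 removals of 1 library in each strain, 8 ended the call of Trib1, 11 that of Per1, 9 that of Ino80c and 11 that of Arl6ip6.

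C57BL/6J held 2125 called genes, against 22 in BALB/cJ and 0 in DBA/2J (limma, with 599 at an unadjusted p under 0.05 and 0 by voom). With the acinar score as a covariate its count was 2365, and without day 5 it was 641 against 581 without day 13, which argues against acinar cells and against a processing series of day 5 as the whole cause. No difference in library depth was seen between HFD (20475594 to 26974401 reads) and RC (19503715 to 32550708), with a two-sided permutation p of 0.745 from 100000 permutations, but this p does not show equal depth, and called genes had a median change of 0.29 at low levels and -0.16 at high levels, so depth is not excluded. With the title number as a covariate the count was 31, but this cannot decide on a processing series that the numbers follow. At day 5 of this strain the number and the diet cannot be told apart, so calls can be lost with or without such a series. At the later days, where the numbers of the diets overlap, the same covariate raised the counts. Such a series stays open as part of the cause. A response that differs by strain, which the design names, remains among the open explanations, with 162 and 186 genes past the test of the difference.

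Clock output genes were higher under HFD on average over strains and days, but at day 13 of DBA/2J all 7 had negative estimates (Dbp -0.56) and Arntl (0.38), Npas2, Clock and Nfil3 positive ones, none called, and none was called in DBA/2J over the days. Collection at another time of day may account for this: Arntl, Npas2, Clock and Nfil3, of the opposite phase, had a median change of -0.74 while 7 output genes had one of 0.61. Across the 69 libraries within groups the scores of both sets had a Pearson r of -0.879 and a Spearman rho of -0.882 (permutation p = 1e-05 each, the smallest the permutations can give, 2 tests), and r was -0.858 without the 2 farthest libraries. By strain r was -0.960 in C57BL/6J, -0.699 in DBA/2J and -0.860 in BALB/cJ. A shift of the clock by the diet itself predicts the same values and stays open, since times of collection were not used here. The islets were kept overnight in culture, so these are levels after culture. Arntl (-1.85), Npas2 (-2.84) and Nfil3 (-1.94) were lowest in C57BL/6J at day 5, while Dbp was highest in BALB/cJ at day 13 (1.75). At day 5 of C57BL/6J a processing series and the diet cannot be told apart.

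The list of DNA replication and mitosis was lower under HFD on average (median -0.26, 11 of 38 genes called, adjusted p = 0.343 with an estimated correlation), but its median was 0.27 in C57BL/6J at day 5 and 0.12 in DBA/2J at day 13. It was -0.20 with the stellate cell and fibroblast score as a covariate and -0.19 with the macrophage and endothelial scores, which argues against the loss of these cells as the whole cause. In BALB/cJ a processing series that the title numbers follow stays open as part of the cause. There the list had a median of -1.15 early minus late at day 13 (13 of 38 genes called) and -0.52 at day 5 (1 called). At both days only the early-numbered HFD libraries had low means. A lower rate of cell division in islet cells under HFD stays open and was not tested apart from these markers.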

How the results depend on the processing

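Alternatives chosen only after the results were seen were voom, days left out, title numbers as a covariate or batch, stellate cell, macrophage and endothelial scores, and the removal of libraries with outlying cell type scores. Of 598 called pairs of named gene and comparison, 510 kept their call under every alternative fixed earlier that keeps all libraries, and 16 changed sign under some alternative. Counts for the strain differences under RC stayed within 1.5 times under every alternative fixed earlier. A change of pseudocount was not run, since the values are on the log2 scale. Where a value moved, the cause was not tested, except that fewer libraries or days give less power. Depth limits genes near the floor of 0.0862 CPM.

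With array weights limma called 3051 genes for all strains, 4876 for C57BL/6J, 159 for DBA/2J and 51 for BALB/cJ. At days 5, 13 and 33 it called 1362, 2743 and 3824 in C57BL/6J, 5990, 18 and 1406 in DBA/2J and 83, 113 and 9 in BALB/cJ. Differences from C57BL/6J were 2112 (DBA/2J) and 1627 (BALB/cJ), and changes with time 889 (C57BL/6J) and 5871 (DBA/2J). With the acinar score as a covariate the counts were 756 at C57BL/6J day 13, 315 at DBA/2J day 5, 2.7e+02 (89 up and 182 down) at BALB/cJ day 5, 552 for DBA/2J minus C57BL/6J and 418 for BALB/cJ minus C57BL/6J. Under RC, Reg1 and Reg3d then turned to -0.56 and -1.19 in DBA/2J minus C57BL/6J and to -0.86 and -0.94 in BALB/cJ minus C57BL/6J.

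With each strain fitted alone limma called 166 at C57BL/6J day 5, 27 at day 13, 0 at DBA/2J day 5, 23 at DBA/2J day 33, 5 for DBA/2J with time, 3 for BALB/cJ over all days, and 0 at BALB/cJ days 5 and 13. With the filter at a mean log2 CPM of 2 the counts were 436 at DBA/2J day 5 and 0 at day 33. With robust empirical Bayes it was 0 at DBA/2J day 33. Quantile normalization gave 1 for DBA/2J, 70 at C57BL/6J day 13, 470 at DBA/2J day 5 and 32 for DBA/2J minus C57BL/6J (10 up, against 95 of 162), left 151 for BALB/cJ minus C57BL/6J (48 up, against 80 of 186), and mt-Co1 turned to 0.13 in BALB/cJ minus C57BL/6J under RC. With libraries shifted to one median BALB/cJ day 5 had 69 (21 up, against 20 of 46) and DBA/2J day 33 had 4 (3 up, against 3 of 3). Blocking on shared title numbers gave 1 for DBA/2J, 3, 1 and 0 at its days, 0 at BALB/cJ day 5, 248 for DBA/2J minus C57BL/6J, 2.9e+02 (88 up and 199 down) for BALB/cJ minus C57BL/6J, and 0 for the change with time in C57BL/6J and DBA/2J. Of the 21 pairs with a shared number 9 had a correlation over 0.1, and 8 correlated best with their own number (range -0.287 to 0.349). Pairing of libraries by number was not shown, and 2 or 3 pairs per strain and day cannot show its absence.

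Without day 5 the counts were 28 for all strains, 641 for C57BL/6J and 6 for BALB/cJ. Without day 13 they were 581 for C57BL/6J, 5 for DBA/2J and 4 for BALB/cJ, and without day 33 439 for all strains and 11 for BALB/cJ. Voom gave 246 at C57BL/6J day 13, 11 at day 33, 0 at DBA/2J day 33, 71 at BALB/cJ day 5, 7 for C57BL/6J with time and 0 for DBA/2J with time. With the title number as a covariate the counts were 428 for all strains, 31 for C57BL/6J, 204 for BALB/cJ, 0, 301 and 8 at the C57BL/6J days, 2 and 3 at DBA/2J days 5 and 13, and 118 at BALB/cJ day 5. Both differences from C57BL/6J and the C57BL/6J change with time were then 0, and BALB/cJ minus C57BL/6J under RC was 5309. In C57BL/6J that setting turned Fn1 to 1.05, Asns to 0.0159, Il1b to 0.0571, Tnfaip3 to 0.0499 and Lyz2 to 0.0891. With the BALB/cJ series as a batch the counts were 80 for BALB/cJ, 429, 329 and 34 at the C57BL/6J days, 2.8e+02 (120 up and 164 down) at DBA/2J day 5, 105 at BALB/cJ day 5, 381 for DBA/2J minus C57BL/6J, and 6 and 5 for C57BL/6J and DBA/2J with time.

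Without libraries of outlying cell type scores the counts were 302 for all strains, 1411 for C57BL/6J, 0 for BALB/cJ, 1 at C57BL/6J day 13, 0 and 1 at DBA/2J days 5 and 33, 0 at BALB/cJ day 13, 3 for DBA/2J minus C57BL/6J, and 1 and 0 for C57BL/6J and DBA/2J with time. The stellate cell score as a covariate gave 397 for all strains, 114 and 7 at C57BL/6J days 5 and 33, 398 at DBA/2J day 5, 24 at BALB/cJ day 5, 103 and 87 for the differences of DBA/2J and BALB/cJ from C57BL/6J, and 4 for DBA/2J with time. The disallowed list then turned to 0.13 for all strains, 0.16 for C57BL/6J and 0.0702 for DBA/2J, and the endothelial list to 0.0103 for all strains.

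Macrophage and endothelial scores as covariates gave 504 for all strains, 1031 for C57BL/6J, 50 and 4 at its days 5 and 33, 199 and 1 at DBA/2J days 5 and 33, 14 at BALB/cJ day 5, 8 and 13 for the differences from C57BL/6J, 144 for DBA/2J with time, and 3382 and 3726 against C57BL/6J under RC. The disallowed list turned to 0.0836 for all strains and 0.16 for C57BL/6J, and the stellate list in C57BL/6J went to -0.0426 with its test turned upward. In DBA/2J minus C57BL/6J under RC, Sst turned to -0.0631, Robo4 to -0.0288, Pdgfrb to -0.0841 and Sox10 to -1.23. In BALB/cJ minus C57BL/6J under RC, Hk1 turned to -0.011, Pdgfrb to -0.17, Cdh19 to -0.0723, Sox10 to -0.53 and Glp1r to -0.14. The endothelial scores of C57BL/6J under RC do not overlap those of the other strains. The RC counts and turns under this covariate therefore cannot show a dependence on cell content.

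Without any 1 library no call of a named gene changed sign. For all strains the count ran from 578 (without C57BL/6J HFD day 13 replicate 4) to 1214 (HFD day 33 replicate 1), and for C57BL/6J from 1298 (HFD day 33 replicate 2) to 2725 (HFD day 33 replicate 1), with 1361 without RC day 33 replicate 1. BALB/cJ ran from 10 (RC day 13 replicate 1) to 58 (HFD day 5 replicate 4), with 10 of 24 removals past 1.5 times, and DBA/2J from 0 to 1 (HFD day 33 replicate 4). C57BL/6J day 5 ran from 61 to 319, with 129, 82 and 61 without HFD replicates 1, 3 and 4, and 81, 100 and 140 without RC replicates 1, 2 and 4. C57BL/6J day 13 ran from 0 to 544, with 544, 3 and 0 without HFD replicates 2, 3 and 4, and 12, 15 and 43 without RC replicates 2 to 4. C57BL/6J day 33 ran from 0 to 1134 (HFD replicate 1) and was at most 4 without any other. DBA/2J day 5 ran from 0 to 1657, with 1436 and 1657 without HFD replicates 1 and 2, 40 without RC replicate 3 and 0 without any other. DBA/2J day 13 ran from 0 to 3 (RC replicate 4), and day 33 from 0 to 1 (RC replicate 2). BALB/cJ day 5 ran from 0 to 356, with 0, 2, 125 and 356 without HFD replicates 1 to 4, and 0, 28 and 4 without RC replicates 1 to 3. BALB/cJ day 13 ran from 0 to 13 (RC replicate 4), and day 33 from 0 to 2 (HFD replicate 3).

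DBA/2J minus C57BL/6J ran from 5 (C57BL/6J HFD day 33 replicate 2) to 524 (C57BL/6J HFD day 13 replicate 2), with 33 of 45 removals past 1.5 times, BALB/cJ minus C57BL/6J from 15 (C57BL/6J HFD day 33 replicate 2) to 514 (BALB/cJ RC day 13 replicate 4), with 30 of 47, and BALB/cJ minus DBA/2J was 0 each time. The change with time ran from 0 to 6 in C57BL/6J (HFD day 5 replicate 1), 0 to 1060 in DBA/2J (HFD day 5 replicate 2; 794 without replicate 1 and 179 without RC day 33 replicate 1) and 0 to 3 in BALB/cJ (RC day 33 replicate 4). Under RC the counts ran from 7390 to 8081 (DBA/2J minus C57BL/6J), 7807 to 8304 (BALB/cJ minus C57BL/6J) and 4706 to 5163 (BALB/cJ minus DBA/2J). Among called named genes 59 of 76 kept their call without any 1 library in C57BL/6J and 49 of 63 over all strains, while 3 of 6 did at C57BL/6J day 5 and none at BALB/cJ day 5, DBA/2J day 5 or C57BL/6J day 13. Calls were kept by 7 of 14 in BALB/cJ, 2 of 15 for DBA/2J minus C57BL/6J and 6 of 16 for BALB/cJ minus C57BL/6J. None was kept for the changes with time. Under RC 117 of 126 (DBA/2J minus C57BL/6J), 131 of 133 (BALB/cJ minus C57BL/6J) and 119 of 124 (BALB/cJ minus DBA/2J) were kept. Of 36 list calls of the average effects none held with an estimated correlation.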

Other observations

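The comparison of title number series, the series as a batch and voom were chosen only after the results were seen, while the comparisons of days, of strains and of other splits were fixed earlier. Gene lists also moved at single days, some as in the averages, and those given here did not hold with an estimated correlation. In BALB/cJ at day 33 the cholesterol list lay lower under HFD (median -0.21, camera adjusted p = 4.67e-10, adjusted p = 0.367 with an estimated correlation), while delta-cell genes lay higher (0.28, 0.000393, adjusted p = 0.129 with an estimated correlation), as did alpha-cell genes (0.24, 0.00135, adjusted p = 0.367 with an estimated correlation) and mitochondrially encoded genes (0.14, 6.89e-05, adjusted p = 0.367 with an estimated correlation). In BALB/cJ at day 13 genes of the integrated stress response lay higher (0.26, 3.71e-05, adjusted p = 0.523 with an estimated correlation), with 6 of 25 higher adjusted over the list alone, and the acinar list lower (-0.69, 0.0178, adjusted p = 0.785 with an estimated correlation).

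In DBA/2J at day 5 ribosomal protein genes lay higher (0.16, 8.23e-09, adjusted p = 0.852 with an estimated correlation) and so did glycolysis genes (0.22, 0.000291, adjusted p = 0.852 with an estimated correlation), 8 of 17 adjusted over the list alone. At day 33 fatty acid oxidation genes lay higher in this strain (0.19, 7.16e-07, adjusted p = 0.811 with an estimated correlation), 5 of 35 adjusted over the list alone. Across genes, which are not independent replicates, the changes of DBA/2J at day 5 and day 13 had an r of -0.223, and 3 of the 80 genes called at day 5 (3.75%) had the same sign at day 13, against 36.8% of all genes. In C57BL/6J the changes at day 5 and day 13 had an r of 0.40.

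Within BALB/cJ, libraries with early title numbers differed from those with later ones in a term fitted at each day over both diets together. The difference was not tested within each diet. At day 5, with 2 HFD and 2 RC libraries early, 812 genes differed, 436 higher in the early ones, and the acinar list had a median of -2.78 early minus late, with 23 of 25 genes called. At day 13, with 2 HFD and 3 RC libraries early, 788 genes differed, 433 higher in the early ones, and 13 of 38 replication genes were called, with a median of -1.15. On the RC side only replicate 4 was late there, and only the early HFD libraries had low means of the replication list. A processing series that the title numbers follow is a candidate explanation for part of the spread, and with the series as a batch the BALB/cJ count rose from 22 to 80.

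Other splits of the same libraries showed how often a count as large as the real one arose. Being the highest of 100 or 35 splits, the real one included, makes chance less likely but does not exclude it. The contrasts were not corrected for their number, and a processing series that goes with the diet would pass as well. As large a count came from 1 of 100 splits for all strains (real 799, highest other 6), for C57BL/6J (2125, 1892), for the difference of DBA/2J from C57BL/6J (162, 59) and that of BALB/cJ from C57BL/6J (186, 181). The same held under RC for DBA/2J minus C57BL/6J (7954, 6189), BALB/cJ minus C57BL/6J (8225, 4068) and BALB/cJ minus DBA/2J (5113, 1744), and in 1 of 35 splits for C57BL/6J day 5 (104 up and 169 down, highest other 48). Chance could not be excluded for BALB/cJ (7 of 100; 22, 934), C57BL/6J day 13 (2 of 35; 152, 168), DBA/2J day 5 (2 of 35; 80, 682), DBA/2J day 33 (2 of 35; 3, 9), BALB/cJ day 5 (4 of 35; 46, 556) and BALB/cJ day 13 (9 of 35; 1, 179). Nor could it for the change with time in C57BL/6J (13 of 100; 3, 2613) and DBA/2J (6 of 100; 2, 1572).

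No count lies below 0, so for counts of 0 by limma the outcome was fixed in advance and says nothing about chance. Such counts were matched by every split. These were 100 of 100 for DBA/2J (highest other 7; 599 genes at an unadjusted p under 0.05, 0 by voom), for BALB/cJ minus DBA/2J (777; 472, 0) and for the change with time in BALB/cJ (426; 706, 0). They were 35 of 35 for C57BL/6J day 33 (2677; 2180, 11), DBA/2J day 13 (12; 599, 0) and BALB/cJ day 33 (48; 669, 0). Splits that called several times the real count point to a structure of the samples. The BALB/cJ day 5 split with 556 genes follows the title numbers, and with that series as a batch the diet count at day 5 was 105. The C57BL/6J day 33 split with 2677 genes sets HFD replicate 1 with the RC libraries against HFD replicates 2, 3 and 4.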
